A study of Mus musculus with 24 samples.

How the data were processed

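Total RNA of BV2 cells and of BV2-derived EVs was extracted with the miRNeasy kit, made into cDNA and libraries with SMART-Seq v4 and Nextera XT with 18 cycles of PCR, and sequenced on a HiSeq X with paired reads of 150 bases, per the labels' protocols. Treatments were LPS at 100 ng/mL, IL-10 at 50 ng/mL and TGF-β at 50 ng/mL for 72 h, per the labels' protocols. The series text also describes recipient cells dosed with EVs, and these are not analysed here. The submitters' processing notes name DESeq2, and its version, the aligner and the genome build are not given in the sources used here.

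The 6 deposited tables hold raw counts, 1 table per treatment and compartment, each with 3 treated and 3 control libraries and the same genes in all. All values in them are whole numbers. The control columns of the 3 tables of a compartment are identical, so the tables were joined into 24 libraries in 8 groups of 3, with 0 columns left unmapped. The columns carry no pairing of replicates. The lowest total of a listed gene over the 24 libraries is 240, a mean of 10 per library, so genes below that level were not in the tables used here. Of the listed genes 116 are at 0 in all cell libraries and 1 is at 0 in all EV libraries. There are 16 names that are numbers, as spreadsheet dates are, and 3 symbols that occur more than once (6 entries), and all were kept in the tests and none was named. Exon lengths came from GENCODE M21 by gene symbol for 13267 entries, and that release may differ from the one the authors used. Tgfbi and P2ry12, which the naming rule includes, are not among the listed genes.

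Comparisons of 3 with 3 libraries were made with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). The main comparisons used the 6 libraries concerned, direct contrasts between treatments used a fit of the 12 libraries of a compartment, and compartment differences used the interaction of compartment and treatment in the 12 libraries concerned. CPM values beside a test are scaled by TMM within that test, and summed CPM and percent values are of library totals. A group with no count was given a floor of 3 counts per library, and its fold is printed as a bound. Of 36 gene lists, 26 were tested and 10 hold markers of other cell types. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry in limma 3.58.1. Sums of genes and shares of counts were compared by exact permutation of the 20 assignments of 6 libraries.

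Before the data were examined, a rule fixed which genes are named: the 8 largest rises and 8 largest falls past the threshold (5 for direct contrasts and compartment differences) with a mean of at least 50 counts in the higher group and no overlap between groups, without unnamed or numbered genes; up to 4 members of each list by adjusted p; 16 genes in all cases, among them Tnf, Nos2, Socs3, Tmem119 and Apoe; and the 3 lowest p-values where nothing passed. A gene outside the rule is marked as chosen after its values were seen. Some genes that the rule names are not reported here. In Lars2, Gm23935 and Gm26917 and in other genes with repeated or nested copies, counts can be shared between loci.

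Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter beyond 1 count, at least 50 counts on average, all libraries of a compartment in the fit, scaling by library size for EVs against cells, and leaving out each library. Added after the data were seen were a minimum of 1000 counts on average and 3 ways of lowering the LPS EV counts, 2 by the level of genes silent in cells and 1 by that of genes with few cell counts. The edgeR procedure was tested on simulated data with 200 changed genes: of 2-fold, 8-fold and 64-fold changes it recovered 81.2%, 100% and 98.3% in LPS cells, and 0%, 3.3% and 30% in LPS EVs. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.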

Results

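RNA was measured in BV2, an immortalised mouse microglial cell line, and in the extracellular vesicles (EVs, membrane particles shed into the medium) of the same line. Cultures were left untreated or given lipopolysaccharide (LPS, 100 ng/mL), a bacterial cell wall component sensed through TLR4, interleukin-10 (IL-10, 50 ng/mL) or transforming growth factor-β (TGF-β, 50 ng/mL) for 72 h. IL-10 and TGF-β are cytokines that restrain inflammatory responses. The 24 libraries formed 8 groups of 3, 1 for each treatment of cells and of EVs. Cell libraries held 26.14 to 42.13 M counts and EV libraries 3.02 to 17.98 M. A count of 0 thus allowed up to 0.071 to 0.115 CPM (counts scaled to library total) in cells and up to 0.167 to 0.994 CPM in EVs (3 counts per library). Between 4.91% and 7.25% of the listed genes had no count in a cell library. In EVs this share was 31.84% ± 2.48 (SD, n = 3) in controls, 31.26% ± 8.08 after IL-10, 32.22% ± 15.85 after TGF-β and 2.04% ± 2.09 after LPS. Across genes, which are not independent replicates, libraries of 1 group correlated with r = 0.992 to 0.996 in cells and r = 0.673 to 0.855 in EVs. Nothing in the labels ties the 3 libraries of a group to separate cultures, so p-values measure the spread between these libraries, which may be technical, and floors cover counting error alone. Unless another unit is named, levels are mean CPM ± SD of n = 3 libraries, and each adjusted p of a gene comes from edgeR's quasi-likelihood test.

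**Figure D1:**
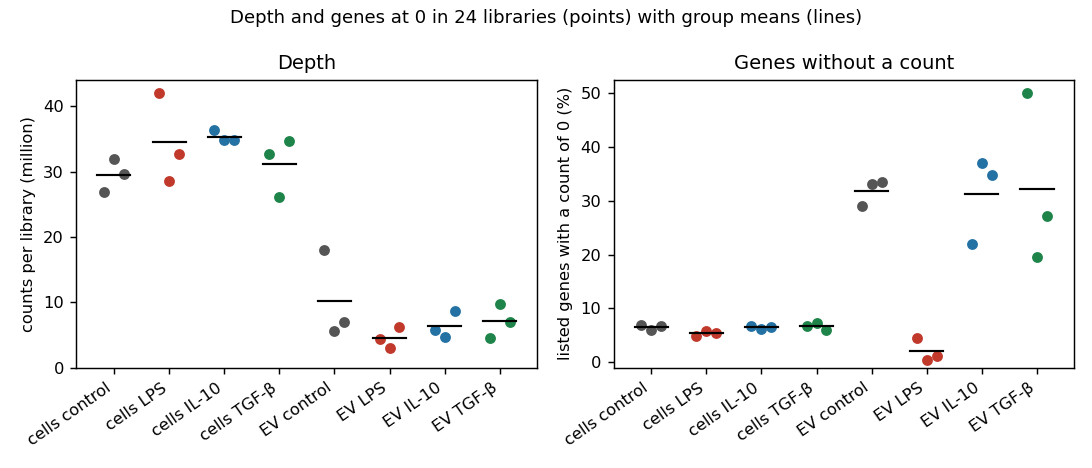
Total counts per library in M (left) and percent of listed genes with a count of 0 (right) for the 8 groups; points are the 24 libraries and lines are group means. EV libraries lie at 3.02 to 17.98 M counts against 26.14 to 42.13 M in cells, and LPS EVs have 2.04% of genes at 0 against 31.84% in control EVs.

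The first comparison asked how LPS changed the RNA of the cells. LPS raised the acute-phase protein Saa3 542-fold (3980 ± 171 against 7.37 ± 0.628 CPM; log2 fold change 9.08, SE 0.09, edgeR adjusted p = 2.72e-22). The scavenger receptor Marco rose 192-fold and Acod1, which makes itaconate, 171-fold (3360 ± 165 against 19.6 ± 2.7). Among cytokines and chemokines, Il1b rose 59.1-fold, Ccl5 53.7-fold and Tnf 33.1-fold (177 ± 24.7 against 5.33 ± 1.14). The inducible nitric oxide synthase Nos2 rose 8.32-fold (641 ± 140 against 77 ± 15.6; adjusted p = 4.57e-05). Several transcripts had no count in any control library. Of these the secreted factor Wfdc21 was at least 220-fold higher, the potassium channel Kcnf1 at least 137-fold, the granulocyte growth factor Csf3 at least 126-fold and the formyl peptide receptor Fpr1 at least 94.5-fold. In the same way complement factor B (Cfb) was at least 93.1-fold higher, the transcription factor Spic at least 87-fold, Adh7 at least 67-fold and Il6 at least 6.92-fold (0.724 ± 0.122 CPM). The iron-binding protein Lcn2 reached 1770 ± 187 CPM from 0.0747 ± 0.129, its 7 control counts all lying in control library 2, without which its log2 fold change is 18.81 in place of 14.35. The largest falls were in F13a1, a coagulation factor subunit made by macrophages (1180-fold, 1300 ± 86.2 to 1.03 ± 0.554), and the arginine-degrading enzyme Arg1 (1170-fold, 279 ± 69.1 to 0.222 ± 0.0909). The lipid kinase Sphk1 fell 130-fold and the chemokine receptor Cxcr2 53.5-fold, and the adhesion molecule Mcam was at least 25.4-fold lower. Cxcl10 rose 164-fold (49.8 ± 5.12 against 0.288 ± 0.218; log2 7.36, or 8.07 without control library 2). The log2 changes of Hspb7 (-7.43), Depp1 (-5.86) and Gpr183 (-5.67) became -8.07, -6.6 and -6.28 without LPS library 1, 2 and 1, respectively.

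Of 11951 tested genes, edgeR called 3421 higher and 3285 lower after LPS at an adjusted p under 0.05, 1003 and 825 of them by more than 2-fold. Between the groups 7457 genes (62.4%, where chance gives 10%) had no overlap. In the list of TLR4 and NF-kB response genes 44 of 47 members rose and 2 fell (44 and 2 adjusted over the list alone; camera adjusted p = 1.31e-87, and adjusted p = 0.0225 with an estimated correlation). The inhibitor Nfkbia rose 14.7-fold. In the type I interferon list 63 of 66 rose and 2 fell (63 and 3 adjusted over the list alone; camera adjusted p = 1.01e-33, adjusted p = 0.0699 with an estimated correlation). Ifit1, Ifit3 and Ifit2, which block viral RNA, rose 67.3-fold, 25.5-fold and 11.2-fold. The interferon-gamma GTPases rose in 12 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 6.6e-12, adjusted p = 0.0225 with an estimated correlation). Among them Gbp2 rose 175-fold and Irgm1 2.85-fold. MHC class I genes and peptide-loading genes rose in 16 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.93e-05, adjusted p = 0.247 with an estimated correlation). H2-T22 rose 3.59-fold, Psme2 2.76-fold and H2-K1 1.38-fold. All 50 listed cell cycle genes rose, such as Rrm2 (4.36-fold) and Cdc6 (3.84-fold; 50 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation). So did 24 of 31 genes of cholesterol and fatty acid synthesis (24 adjusted over the list alone; adjusted p = 0.0758 with an estimated correlation), such as Insig1 (5.67-fold) and Mvd (3.61-fold). NRF2 targets of the oxidative stress response rose in 15 of 22 cases and fell in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.0402 with an estimated correlation). Glutathione reductase (Gsr) rose 5.35-fold and the peroxidase Prdx1 2.93-fold. Proteasome subunits rose in 31 of 37 cases and fell in 2 (32 and 2 adjusted over the list alone), with Psmd10 2.86-fold higher and an adjusted p = 0.288 with an estimated correlation.

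Other lists moved down or both ways in LPS cells. Homeostatic microglial genes fell in 16 of 28 cases and rose in 7 (16 and 7 adjusted over the list alone; camera adjusted p = 1.93e-05, adjusted p = 0.0402 with an estimated correlation). The ectonucleotidase Entpd1 fell 4.45-fold and the phagocytic receptor Mertk 4.32-fold. The microglial surface protein Tmem119 rose 2.28-fold (26.7 ± 4.09 against 11.7 ± 2.15 CPM; edgeR adjusted p = 1.51e-06). The fractalkine receptor Cx3cr1 was near the floor in both groups (0.0116 ± 0.0201 and 0.081 ± 0.0845 CPM) and was not tested. Genes of alternative activation fell in 10 of 15 cases and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.0225 with an estimated correlation), including the mannose receptor Mrc1 (5.22-fold). In the list of disease-associated microglia 23 of 32 fell and 6 rose (24 and 6 adjusted over the list alone; camera adjusted p = 5.62e-09, adjusted p = 0.158 with an estimated correlation). The lipid carrier Apoe fell 4.98-fold (3200 ± 80.2 against 16000 ± 468) and the integrin Itgax 5.36-fold, while Cd52 rose 4.84-fold. Glycolysis and hypoxia genes fell in 24 of 33 cases and rose in 7 (24 and 7 adjusted over the list alone; adjusted p = 0.152 with an estimated correlation), with Ndrg1 down 10.5-fold and Egln3 8.12-fold. Lysosomal genes fell in 24 of 36 cases and rose in 6 (26 and 6 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation), with the proton pump subunit Atp6v0d2 down 11.1-fold. Among vesicle genes (tetraspanins, annexins and ESCRT components) 19 of 36 fell and 3 rose (19 and 3 adjusted over the list alone; adjusted p = 0.0739 with an estimated correlation). Anxa1 fell 3.24-fold, Cd9 2.11-fold and the exosome tetraspanin Cd63 1.53-fold. Complement and phagocytic receptor genes went both ways, 8 up and 11 down of 20 (9 and 11 adjusted over the list alone; median log2 fold change -0.231, mean 0.367), with C3 up 8.3-fold and C4b down 14.9-fold. TGF-β and SMAD targets fell in 13 of 29 cases and rose in 7 (median -0.164, mean 0.162), the SMAD inhibitor Smad7 falling 2.99-fold (13 and 7 adjusted over the list alone). IL-10 and STAT3 targets rose in 13 of 31 and fell in 12 (13 and 13 adjusted over the list alone; median 0.085, mean -0.038), Socs3 rising 2.17-fold. Reads from Ifit, Gbp, H2 and histone genes and from C4b can be shared with near-identical copies, so values of single members of these families are uncertain in all comparisons here.

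**Figure D2:**
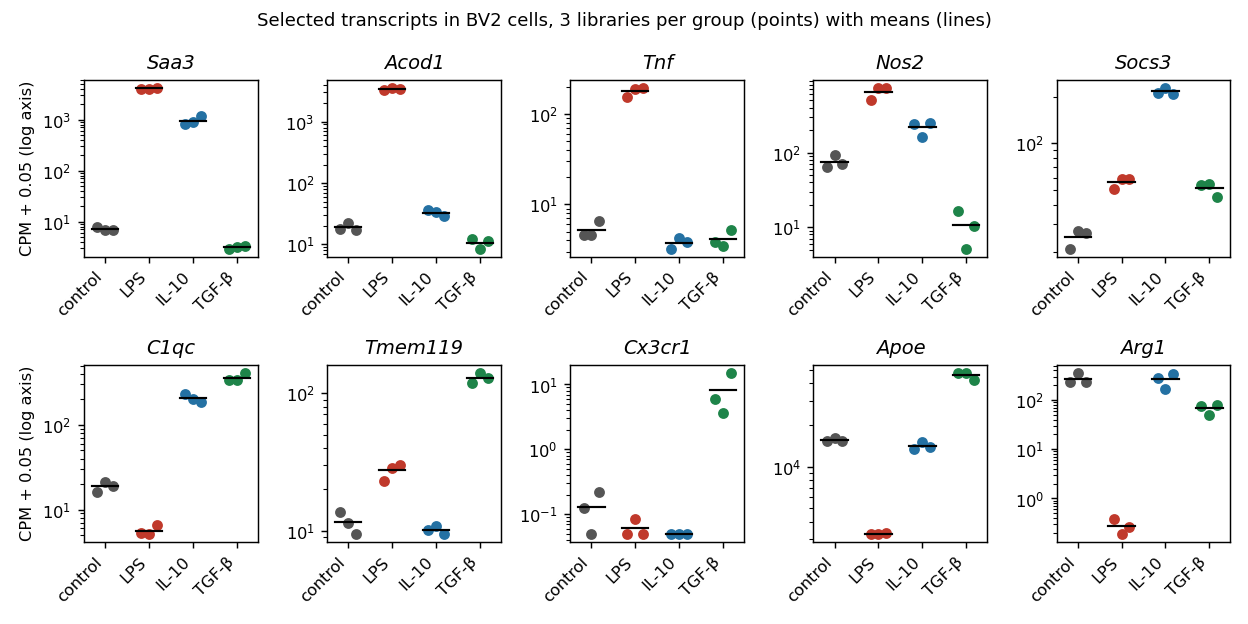
CPM + 0.05 on log axes for 10 transcripts in the 4 cell groups; points are the 3 libraries of a group and lines are means. In CPM of library totals Saa3 reaches 4080 after LPS and 955 after IL-10 from 7.2 in controls. Socs3 is highest after IL-10, and C1qc, Tmem119, Cx3cr1 and Apoe are highest after TGF-β.

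The second comparison concerned IL-10, which signals through STAT3. The STAT3 feedback inhibitor Socs3 rose 9.72-fold (228 ± 12.4 against 23.4 ± 3.06 CPM; log2 fold change 3.28, SE 0.09, edgeR adjusted p = 1.41e-14). The classical complement genes C1qc (12.3-fold, 218 ± 19.7 against 17.7 ± 2.32), C4b (6.09-fold) and C1qb (5.85-fold) rose with it. The largest rises were in Ly6a, a GPI-anchored surface antigen (355-fold, 62.1 ± 9.42 against 0.167 ± 0.084), Saa3 (148-fold, 1010 ± 208 against 6.82 ± 0.59) and Lrg1 (121-fold). The chemokine Ccl8 was at least 59.3-fold and Ly6c1 at least 56.4-fold higher than in controls, which had no count of either. Spp1, which encodes osteopontin, rose 4.55-fold to 46900 ± 5080 CPM. The glycosyltransferase A4galt rose 74.6-fold (log2 6.22, or 6.99 without control library 3), and Nnmt reached 2.27 ± 0.206 from 0.0205 ± 0.0178 CPM. Nxpe5 reached 3.58 ± 0.735 from 0.0332 ± 0.0322 (log2 6.64, or 6.04 and 7.49 without control library 2 and 3). Falls were smaller: Mamdc2 fell 12-fold, the fatty acid hydroxylase Cyp4f18 6.55-fold, Depp1 6.16-fold, Dusp27 5.01-fold, Peg10 4.84-fold and Sema5b 4.75-fold. The log2 changes of Arhgap22 (-3.05) and Lamb2 (-2.2) were -3.95 without IL-10 library 2 and -2.96 without IL-10 library 1. The inflammatory genes split: Nos2 rose 3.22-fold (229 ± 49.9 against 71.2 ± 14; edgeR adjusted p = 0.00725) and Acod1 1.91-fold (adjusted p = 9.11e-06). Tnf (3.94 ± 0.581 against 4.94 ± 1.09; edgeR adjusted p = 0.332) and Cxcl10 (0.627 ± 0.137 against 0.266 ± 0.2; adjusted p = 0.183) did not pass. The log2 change of Cxcl10 was 1.19, or 1.89 without control library 2, where it did not pass either. Il1b was at 8.19 ± 2.45 against 9.57 ± 0.527 (edgeR adjusted p = 0.431, and 0.0468 without IL-10 library 1). Ccl5 rose 2.01-fold (adjusted p = 0.00902) but not without control library 2 (0.0564) or 3 (0.0575). Tmem119 (10.6 ± 0.68 against 10.8 ± 1.97; edgeR adjusted p = 0.922) and Apoe (15000 ± 923 against 14800 ± 327; log2 0.02, SE 0.05) did not pass either. Smad7 was at 2.05 ± 0.375 against 3.09 ± 0.771 CPM (edgeR adjusted p = 0.153).

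In all, edgeR called 1447 genes higher and 1286 lower among 11790 (192 and 114 by more than 2-fold). There were 4470 genes (37.91%, chance 10%) without overlap between IL-10 and control cells. IL-10 and STAT3 targets rose in 15 of 31 cases and fell in 3 (18 and 4 adjusted over the list alone; camera adjusted p = 3.4e-26, adjusted p = 0.0186 with an estimated correlation). The scavenger receptor Msr1 rose 8.67-fold, Sbno2 2.94-fold and the haem-degrading enzyme Hmox1 2.69-fold. Complement and phagocytic receptor genes rose in 14 of 20 cases and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.0305 with an estimated correlation). MHC class I genes rose in 13 of 20 with none lower (15 adjusted over the list alone; adjusted p = 0.0305 with an estimated correlation), H2-K1 rising 1.84-fold and B2m 1.57-fold. Homeostatic genes rose in 13 of 30 with 6 lower (13 and 7 adjusted over the list alone; adjusted p = 0.0347 with an estimated correlation). Further lists passed camera with its preset correlation and lost the call with an estimated one. Disease-associated genes rose in 20 of 32 cases and fell in 3, with Fabp5 2.4-fold and the cathepsin Ctsb 2.07-fold higher (20 and 3 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). Lysosomal genes rose in 19 of 36 and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation), Lamp2 rising 1.59-fold. Type I interferon genes rose in 28 of 63 cases and fell in 1 (36 and 1 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), such as Ly6e (2.12-fold) and the nucleic acid sensor Zbp1 (4.05-fold). NF-kB response genes rose in 17 of 40 and fell in 6 (19 and 8 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with Icam1 1.66-fold and Cd40 1.79-fold higher. Vesicle genes rose in 16 of 36 and fell in 3 (17 and 4 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation), Sdcbp rising 1.58-fold and Cd63 1.23-fold. Of the genes of oxidative phosphorylation 25 of 79 rose with none lower (27 adjusted over the list alone; adjusted p = 0.484 with an estimated correlation).

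The third comparison asked what TGF-β changed in the cells. Olfml3, a secreted protein of microglia, rose 2220-fold (335 ± 11.8 against 0.151 ± 0.0987 CPM; log2 fold change 11.12, SE 0.16, edgeR adjusted p = 6.41e-14). Microglial identity genes rose with it, C1qa 119-fold (19.3 ± 9.75 against 0.164 ± 0.099) and C1qc 19.2-fold (360 ± 31.6 against 18.7 ± 2.49). Tmem119 rose 11.4-fold (130 ± 10.9 against 11.4 ± 2.04; adjusted p = 1.57e-09). Cx3cr1 reached 8.06 ± 5.74 from 0.0813 ± 0.085 CPM (log2 6.6, SE 0.91, edgeR adjusted p = 0.00209; 5.85 without TGF-β library 3 and 5.99 or 7.74 without control library 2 or 3). Apoe rose 2.94-fold to 45700 ± 4130 CPM, Apoc1 27.2-fold, and the SMAD targets Id3 and Skil rose 16.5-fold and 15.8-fold. Kynu, an enzyme of tryptophan breakdown, rose 40.6-fold, and Ush1g, without a control count, was at least 74.8-fold higher. Spsb1 reached 18.2 ± 1.25 from 0.0351 ± 0.0373 CPM (3 control counts), the chemokine Cxcl14 6.41 ± 1.36 and the junction protein F11r 2.14 ± 1.25, the last 2 from 1 control count each. Falls were led by Gas7, which lost all its counts (at least 203-fold, from 19.9 ± 0.642 CPM), and the elastase Mmp12 (28.4-fold, 93.7 ± 5.93 to 3.29 ± 0.413). Also lower were properdin (Cfp, 20.7-fold), Syn1 (18.9-fold), and Pilrb1 and the chemokine receptor Ccr1 (14.7-fold each). The log2 change of Klk1b11 (-5.65) was -5.04 without TGF-β library 1 and -6.36 without TGF-β library 2. That of Gbp7 (-5.3) was -6.65 without TGF-β library 3. Of the inflammatory genes, Ccl5 fell 5.72-fold, Il1b 1.89-fold (edgeR adjusted p = 0.00111) and Acod1 1.79-fold. Nos2 fell 7.02-fold (10.6 ± 5.69 against 75 ± 14.8; edgeR adjusted p = 0.0128, and 0.0617 without TGF-β library 3), and Tnf was at 4.07 ± 0.81 against 5.2 ± 1.16 CPM (adjusted p = 0.297). The feedback inhibitor Smad7 was at 7.66 ± 4.9 against 3.26 ± 0.811 (log2 1.23, or 0.59 without TGF-β library 1; edgeR adjusted p = 0.0744). It passed without TGF-β library 2 (0.017), with all 12 cell libraries in the fit (0.0118) and in DESeq2 (0.00302). Cd63 was at 2050 ± 259 against 1760 ± 61.8 (edgeR adjusted p = 0.0726), passing without TGF-β library 3 (0.000664), in limma-voom (0.00919) and with all 12 libraries (0.0491).

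TGF-β gave 1715 higher and 1818 lower genes of 11798 in edgeR (377 and 439 by more than 2-fold), and 5299 genes (44.91%, chance 10%) did not overlap. Homeostatic microglial genes rose in 22 of 31 cases and fell in 3 (24 and 4 adjusted over the list alone; camera adjusted p = 7.48e-38, adjusted p = 0.013 with an estimated correlation). NRF2 targets fell in 16 of 22 cases with none higher (18 adjusted over the list alone; adjusted p = 0.013 with an estimated correlation), the antioxidant enzymes Srxn1, Prdx1 and Blvrb falling 2.8-fold, 2.04-fold and 2.12-fold. LXR targets rose in 6 of 8 cases with none lower (6 adjusted over the list alone; adjusted p = 0.0463 with an estimated correlation), for example Mylip (1.96-fold) and Lpcat3 (1.77-fold). The lists that follow passed camera with its preset correlation and lost the call with an estimated one. TGF-β and SMAD targets rose in 14 of 28 cases and fell in 4 (16 and 6 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), including Smad6 (6.97-fold) and the integrin Itgav (5.99-fold). Type I interferon genes fell in 37 of 58 cases and rose in 3 (38 and 4 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), Oasl1 by 4.37-fold and Slfn2 by 3.09-fold. MHC class I genes fell in 10 of 20 with none higher (10 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), H2-K1 by 1.49-fold. NF-kB response genes fell in 23 of 40 cases and rose in 7 (25 and 9 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Il1rn fell 7.99-fold and Cd14 2.62-fold, and the receptor Tlr2 rose 3.62-fold. Unfolded protein and integrated stress response genes fell in 19 of 34 cases and rose in 12 (20 and 13 adjusted over the list alone; adjusted p = 0.0718 with an estimated correlation), Slc7a11 falling 4.39-fold. Genes of alternative activation fell in 7 of 15 and rose in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.0606 with an estimated correlation), Myc falling 3.81-fold. Cholesterol and fatty acid synthesis genes rose in 16 of 31 cases and fell in 3 (17 and 4 adjusted over the list alone; adjusted p = 0.505 with an estimated correlation), such as Srebf1 (2.98-fold). Antigen presentation by MHC class II did not pass as a list (camera adjusted p = 0.161), although 7 of its 9 members rose and 1 fell (7 and 2 adjusted over the list alone). The cathepsin Ctss was 1.97-fold higher and the invariant chain Cd74 5.67-fold lower. Socs3 rose 2.08-fold and Spp1 2.47-fold.

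**Figure D3:**
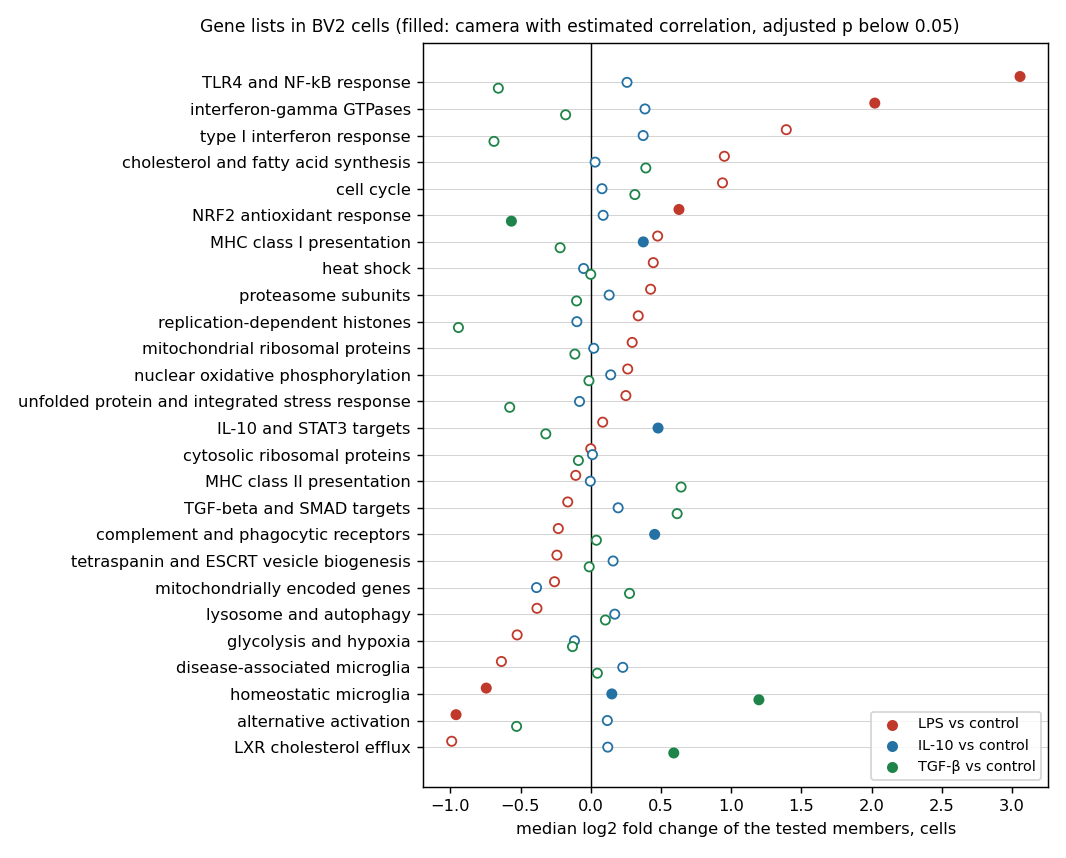
Median log2 fold change of the tested members of each gene list in LPS, IL-10 and TGF-β cells against control cells, one row per list; each point is one treatment, filled where the list passed camera with an estimated correlation (adjusted p under 0.05). Filled points include TLR4 and NF-kB genes after LPS (median 3.06), complement and STAT3 target lists after IL-10 and homeostatic genes after TGF-β.

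Treated cells were also compared with each other, since the series title speaks of state-specific signatures. LPS and IL-10 cells differed in 6469 of 12148 genes (3279 higher and 3190 lower after LPS), LPS and TGF-β cells in 6939 (3560 and 3379), by edgeR. TGF-β and IL-10 cells differed in 4649 (2223 higher and 2426 lower after TGF-β). Against IL-10 cells, LPS cells held 1710 ± 198 CPM of Lcn2 in place of 0.487 ± 0.0726 (log2 fold change 11.77, SE 0.23). Kcnf1, Csf3, Susd2 and Cd300e were at least 148-fold, 136-fold, 122-fold and 116-fold higher. F13a1, Arg1, the secreted macrophage protein Cd5l and Lrg1 were 1670-fold, 1260-fold, 210-fold and 148-fold lower. Against TGF-β cells, Gas7, Wfdc21, Csf3 and the chemokine Cxcl2 were at least 657-fold, 229-fold, 131-fold and 105-fold higher after LPS, and Mcam, Capn3 and Ush1g at least 234-fold, 120-fold and 89.5-fold lower, with Olfml3 1450-fold lower. Between the cytokines, Ly6a, Gas7, Ccl8, the water channel Aqp8 and Nxpe5 were at least 667-fold, 212-fold, 61.8-fold, 46.1-fold and 38.4-fold lower in TGF-β cells. Cx3cr1 and Ush1g were there at least 85.2-fold and 80.7-fold higher and Cyp4f18 was 103-fold higher (227 ± 14.8 against 2.21 ± 0.487 CPM). Olfml3 was at 330 ± 11.7 against 0.139 ± 0.215 CPM (log2 11.12, or 14.03 without IL-10 library 1).

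The calls of the 3 treatments overlapped in part. LPS and IL-10 raised 587 genes in common, lowered 732 and moved 596 opposite ways (199 raised by LPS, 397 lowered). Independent lists give 399.4 and 360.2 in common and 358.5 and 401.4 opposite, and unchanged groups simulated against the same controls gave 0 and 0 in common. LPS and TGF-β shared 516 raised and 779 lowered genes (465.1 and 510.3 for independent lists, 0 and 0.05 simulated) against 1082 that went opposite ways, 541 each way (503.9 raised and 471 lowered by LPS for independent lists). IL-10 and TGF-β shared 385 and 448 (204 and 200 for independent lists, 0 and 0.05 simulated) against 467 opposite, 301 raised and 166 lowered by IL-10 (220.9 and 184.7 for independent lists). Log2 fold changes correlated across genes with r = 0.32 for LPS and IL-10, 0.039 for LPS and TGF-β and 0.191 for IL-10 and TGF-β, where shared controls alone gave 0.517, 0.517 and 0.511 in simulation. The covariances were 0.1395, 0.023 and 0.058 against simulated values of 0.0241, 0.0265 and 0.0279. With 3 control libraries no split with 2 per part was possible, so part of the excess of shared calls may come from the shared controls. In groups simulated as unchanged few genes should pass, so their shared counts cannot gauge this part.

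Control EVs were compared with control cells to ask which RNAs the vesicles carry. Lcn2 was at 216 ± 162 CPM in control EVs against 0.072 ± 0.125 in control cells (log2 fold change 11.37, SE 1.85, edgeR adjusted p = 0.0216). Saa3 was at 1020 ± 571 against 7.13 ± 0.614 (143-fold, adjusted p = 0.0216). LPS had raised both in cells. The cytoskeletal regulator Enah was 553-fold higher in EVs, the retinaldehyde oxidising enzyme Aldh1a3 472-fold, Pdzd2 359-fold (516 ± 427 against 1.43 ± 0.482), and Wfdc21 at least 62.8-fold. The microRNA locus Mir3473a was 738-fold higher, while Arhgef40 (92.7 ± 81.9 CPM) and Unc13d (14.2 ± 12.6 CPM) stood against 3 counts and 1 count in cells. Rpap1, which assists RNA polymerase II assembly, had no count in control EVs and 80.5 ± 4.33 CPM in control cells (at least 205-fold lower). Ccnf, the kinase Aatk, Ift140 and Kif3c were at least 182-fold, 180-fold, 122-fold and 117-fold lower, Dcaf1, Foxred2 and Wdr62 at least 111-fold, 110-fold and 107-fold. Tmem119 was at least 28.9-fold lower in EVs, Myc at least 39-fold, the fatty acid transporter Cd36 at least 43.9-fold, Smad3 at least 38-fold, and the transcription factor Cebpb 20.2-fold lower. Insig1 and Mvd of sterol synthesis were 3.6-fold and 2.71-fold higher and Nfkbia 3.31-fold, while the AP-1 subunit Jun, the sterol exporter Abcg1 and prosaposin (Psap) were 2.65-fold, 3.86-fold and 2.52-fold lower. Apoe (12500 ± 2200 against 15400 ± 394; edgeR adjusted p = 0.455), Cd63 (1490 ± 359 against 1750 ± 60.4; 0.698) and H2-K1 (772 ± 303 against 1140 ± 12.4; 0.431) did not pass. Neither did Tnf (36.4 ± 36.4 against 5.16 ± 1.12; edgeR adjusted p = 0.141), Il1b (0.13), Ccl5 (0.0769) and Acod1 (416 ± 412 against 19 ± 2.54; 0.0764). The kit does not mark strand, so Mir3473a counts cannot be told from those of an overlapping transcript.

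In edgeR 140 genes were higher and 1078 lower in EVs among 11427 tested (median log2 fold change of all genes -0.237), and 4725 (41.35%, chance 10%) did not overlap. DESeq2 called 1185 higher and 1850 lower, edgeR with all 24 libraries 650 and 1215, and edgeR with at least 50 counts on average 62 and 487. No gene passed when any 1 control cell library was left out, and 4175, 2040 or 1984 passed without control EV library 1, 2 or 3. Cells and EVs shared 1 spread per gene in these fits, so p-values may be too small for the more variable EVs. Cytosolic ribosomal protein genes had a median log2 difference of 1.45 (camera adjusted p = 5.85e-32, adjusted p = 0.617 with an estimated correlation), with 1 of 82 called over all genes (Rps27l, 2.57-fold) and 56 higher adjusted over the list alone. TGF-β and SMAD targets were lower in EVs in 7 of 25 cases (8 lower and 1 higher adjusted over the list alone; median -1.574, or -1.006 with genes at 0 set to their bound; adjusted p = 0.616 with an estimated correlation). NF-kB response genes were higher in 5 of 40 (5 adjusted over the list alone; adjusted p = 0.617 with an estimated correlation). Genes of oxidative phosphorylation (2 higher and 1 lower of 79), mitochondrial ribosomes (1 higher of 74), proteasome subunits (1 higher of 37), the cell cycle (1 higher and 1 lower of 50) and cholesterol synthesis (3 higher of 31) passed singly. Each of these lists passed camera upward with its preset correlation and none with an estimated one (adjusted p = 0.502, 0.194, 0.842, 0.617 and 0.617 with an estimated correlation). Adjusted over the list alone these counts were 0, 0, 0, 0 higher with 1 lower, and 3 higher.

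EVs from LPS-treated cells were compared with control EVs for the vesicle response to LPS. The inflammatory cytokine Il1b rose 16.8-fold (865 ± 324 against 51.3 ± 40.8 CPM; log2 fold change 4.07, SE 0.71, edgeR adjusted p = 0.025). The chemokines Cxcl10 and Ccl5 rose 55.7-fold (579 ± 214 against 10.3 ± 9.2; adjusted p = 0.0301) and 8.06-fold (296 ± 143 against 36.6 ± 22.8; adjusted p = 0.0255). The stress transcripts Ddit3 and Ier3 rose 6.18-fold and 4.07-fold. Csf3, Osmr, the interferon-induced Ifit3b and Parp14, and Il6 were at least 124-fold, 98.6-fold, 91.6-fold, 89-fold and 26.4-fold higher, without a count in control EVs. Il6 had 19, 78 and 57 counts in the LPS EV libraries, below the median of genes silent in cells (43, 128 and 120). The 8 largest rises were all from 0 in control EVs: the muscle giant Ttn (at least 483-fold, 202 ± 128 CPM), the nuclear envelope protein Syne2 (184-fold), and Rpap1 (181-fold). Then came the calcium channel Cacna1e (176-fold), the axonemal dynein Dnah8 (154-fold), Rtp4 (152-fold), the synaptic scaffold Dlgap1 (151-fold) and the nuclease Gen1 (147-fold), and each of the 8 values is a lower bound on the ratio of counts alone. All bounds in this comparison ignore the reads that LPS EVs hold at genes silent in cells. They are thus no bounds on a rise of vesicle RNA. Tmem119 was at least 27.6-fold higher (11.5 ± 11 CPM; edgeR adjusted p = 0.0269), with 22, 19 and 159 counts, below the silent-gene median in 2 of 3 libraries. Gng7, a G protein subunit, stood at 0.137 ± 0.13 CPM (2 counts in all) against 31.9 ± 4.96. Klhl9 fell 11.4-fold, Acap2 8.16-fold, the stress sensor Sesn2 7-fold, the helicase Ddx19b 5.94-fold, Ndst1 5.13-fold, Sh2d3c 5.04-fold and Arhgap19 4.83-fold. Tnf (40.8 ± 10.7 against 39.2 ± 39.6; edgeR adjusted p = 0.992), Nos2 (53.2 ± 16 against 47.1 ± 22.5; 0.966), and Acod1 (1390 ± 522 against 447 ± 441; 0.47) did not pass. Neither did Socs3 (edgeR adjusted p = 0.374), Smad7 (0.0849), Apoe (6820 ± 4910 against 13300 ± 2270; 0.534), H2-K1 (0.153) or Cd63 (0.803).

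Among 12216 genes edgeR called 1703 higher and 29 lower in LPS EVs, while 3880 (31.76%, chance 10%) did not overlap and the median of all genes was 0.327 on the log2 scale. In simulated data of this comparison edgeR recovered 18 of 60 64-fold changes, and 17 of these were among the 30 rises. Falls were thus rarely called even where present, so the 2 counts do not measure the balance of rises and falls. Genes silent in cells moved with the LPS EVs. At 423 genes with at most 3 counts in every cell library, which can be listed only because EV reads carry them, the median count was 43, 128 and 120 in the LPS EV libraries and 0 in all other libraries. These genes took 0.462%, 1.937% and 0.848% of the LPS EV counts and at most 0.036% of any other EV library. Neuronal marker genes summed to 95 ± 77.1 CPM in LPS EVs against 3.88 ± 5.13 in control EVs, fibroblast markers to 36.9 ± 26.4 against 0 and lymphocyte markers to 30.6 ± 19.7 against 2.99 ± 5.02. Astrocyte markers stood at 264 ± 156 against 206 ± 105 and neutrophil markers at 85.3 ± 4 against 91.5 ± 70.8. Type I interferon genes rose in 14 of 66 cases (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000847, adjusted p = 0.447 with an estimated correlation). NF-kB response genes rose in 6 of 46 (6 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation) and TGF-β and SMAD targets in 7 of 27 (8 adjusted over the list alone; camera adjusted p = 0.313). Disease-associated genes lay lower as a list (median -0.866; camera adjusted p = 3.73e-08, adjusted p = 0.447 with an estimated correlation) although the 2 of 33 that passed rose (2 adjusted over the list alone). Lysosomal genes lay lower too (1 of 35 passing, higher, and 0 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation). Mitochondrial transcripts had a median of -1.446, 1 of 10 passing (mt-Nd5, 3.35-fold lower; 1 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation). No gene passed in edgeR without LPS EV library 1, 2 or 3 (2599 without control EV library 1, 2481 higher and 118 lower). DESeq2 called 2685 genes, 2457 higher and 228 lower, and limma-voom 3038, 2989 and 49. None passed in edgeR with all 12 EV libraries in the fit (2425 at an unadjusted p under 0.05) or with at least 50 counts per gene on average (1220). A minimum of 1000 counts on average, chosen after the values were seen, gave 7 calls, all higher (Ier3, Rbm25, Cyb5r3, Ccl9, Ddit3, Il1b and the uncharacterised Gm23935). Lowering the LPS EV counts, also chosen afterwards, by each library's median at silent genes left 2 calls, Gm23935 and Gm29371. That amount overstates a background, since silent genes are listed only because EV reads carry them. Genes with few cell counts, listed whatever their EV counts, had medians of 11, 25 and 28, and lowering by these left 0 calls.

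IL-10 and TGF-β gave no called gene in EVs. After IL-10, 0 of 8992 genes passed in edgeR (177 at an unadjusted p under 0.05, 90 calls in DESeq2) and 894 (9.94%, chance 10%) did not overlap. After TGF-β it was 0 of 9093 in edgeR (360 at an unadjusted p under 0.05, 121 calls in DESeq2) and 1541 (16.95%). The integrin Itga5 had no count in IL-10 EVs and 165 ± 25.2 CPM in control EVs (edgeR adjusted p = 0.295), Icam1 0 against 63.4 ± 21.4 and Mctp1 0 against 55.7 ± 33.9 (adjusted p = 1 each). Socs3, raised in IL-10 cells, was at 61.1 ± 38.1 against 65.3 ± 46.3. In TGF-β EVs Klhl25 was at 122 ± 11.8 CPM against 0 (edgeR adjusted p = 0.723), Cd99l2 at 286 ± 132 against 23 ± 2.69, and the noncoding Gm26917 at 22.2 ± 5.41 against 188 ± 48.1. Tmem119 was at 53.6 ± 37.3 against 0 and Apoe at 3200 ± 814 against 11400 ± 1830 (adjusted p = 0.999 each). Ribosomal protein genes lay higher as a list in both (median log2 difference 0.587 after IL-10 and 0.646 after TGF-β; camera adjusted p = 1.93e-09 and 1.25e-08, adjusted p = 0.694 and 0.5 with an estimated correlation). Disease-associated genes lay lower after TGF-β (median -1.248; camera adjusted p = 1.22e-11, adjusted p = 0.468 with an estimated correlation). For TGF-β the median of all genes was -0.133 with TMM and -0.238 with RLE scaling, and all values of that comparison shift with it. In simulated EV data edgeR recovered 40% of 64-fold changes and 1.7% of 8-fold changes for IL-10, and 30% and 0% for TGF-β. Of the 64-fold rises alone it recovered 20 of 30 for IL-10 and 13 of 30 for TGF-β. Most 8-fold changes and most 64-fold falls would thus have been missed here.

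Direct contrasts of EV groups gave 6 calls between LPS and TGF-β EVs, 3 in each direction, all by edgeR in the fit of 12 libraries. The mitochondrial leucyl-tRNA synthetase Lars2 was 19-fold higher in LPS EVs (2270 ± 638 against 120 ± 45.3 CPM; log2 4.24, SE 0.48, edgeR adjusted p = 0.0126). So were Gm23935 (log2 4.67) and Gm26917 (log2 3.81), outside the naming rule and singled out after their values were seen. Counts of these 3 genes can be shared between loci, so a change of Lars2 mRNA does not follow. Lower were Dgkd (94.5 ± 11.4 against 912 ± 137; log2 -3.27, edgeR adjusted p = 0.0165), Poldip2 (-2.48, 0.0484) and Arhgap19 (-4.13, 0.0495). Leaving out any 1 library left 0 to 2 calls, DESeq2 gave 1205, and 23 passed in edgeR after the LPS EV counts were lowered by the silent-gene median (4 with the smaller amount from genes with few cell counts). LPS and IL-10 EVs gave 0 calls in edgeR (2453 at an unadjusted p under 0.05, 1012 in DESeq2), and TGF-β and IL-10 EVs 0 (790 and 285).

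Whether a treatment acted differently on cells and EVs was tested as an interaction. Cells and EVs shared 1 spread per gene in this test. Fitted alone, the spread beyond counting was 10.7% in the IL-10 comparison of cells and 129.3% in that of EVs. The p-values of the interactions may thus be too small for changes in EVs. For LPS, edgeR found 2135 of 13263 genes, 1864 with a more positive change in EVs and 271 with a more negative one. After the LPS EV counts were lowered by the median of genes with few cell counts, a setting chosen after the data were seen, 1254 were called, 1002 positive and 252 negative. The silent-gene median, which overstates a background, turned the direction (788 called, 186 positive and 602 negative). With at least 50 counts on average 842 were called. Lcn2 rose in LPS cells but was at 296 ± 69 against 232 ± 176 CPM in EVs (interaction log2 -13.99, edgeR adjusted p = 0.00143). Control cells held 0.0731 ± 0.127 CPM of library totals, so the difference rests in part on the high level in control EVs. Gng7 was at 0.119 ± 0.111 against 31.9 ± 4.73 in EVs (log2 -7.72, adjusted p = 0.00146). For IL-10 there were 34 such genes, 13 positive and 21 negative, among them Itga5 (edgeR adjusted p = 2.44e-05) and Icam1 (0.000675), both without a count in IL-10 EVs and neither called in EVs alone. For TGF-β there were 37, 16 positive and 21 negative, among them Klhl25 (0.00296). DESeq2 called 703 for IL-10 (373 positive, 330 negative) and 785 for TGF-β (464 and 321). These calls moved with single libraries: 2 to 272 for IL-10 and 3 to 432 for TGF-β with 1 library left out. The lowest came without control cell library 3 for IL-10 and without any 1 cell library for TGF-β, the highest without IL-10 EV library 3 and TGF-β EV library 2. Their direction moved too: for TGF-β 92 were positive and 340 negative without EV library 2, and 232 and 64 without EV library 1. For IL-10 it was 50 and 189 without EV library 1, and 94 and 58 without EV library 2. For LPS the range was 1575 to 3587, the highest without control EV library 1.

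Transcripts specific to 1 treated cell group were then followed into the EVs, by a rule set after the tables were seen: at least 5 CPM in that group and at least 8-fold above all other cell groups. The 90 genes specific to LPS cells summed to 16240 ± 745.7 CPM in LPS cells, 476.9 ± 19.22 in control cells and 10440 ± 1520 in LPS EVs. Control EVs held 2461 ± 1735 CPM of them (exact permutation p = 0.1, the smallest that 3 against 3 can give), IL-10 EVs 2085 ± 2396 and TGF-β EVs 1209 ± 1513. In each of the IL-10 and TGF-β EV groups 1 library carried most of the mean. The IL-10 EV libraries held 810.4, 595.6 and 4849 CPM, and the TGF-β EV libraries 304.7, 2956 and 365.5. The 15 genes specific to TGF-β cells summed to 833.4 ± 31.16 CPM there, 27.11 ± 3.756 in control cells, 308.1 ± 91.88 in TGF-β EVs and 121.1 ± 130.5 in control EVs (exact permutation p = 0.2). In the TGF-β EV libraries 1 gene, AU020206, singled out after the values were seen, made up 95%, 76.9% and 79.3% of the sum, and 6 of the 15 genes were detected on average, against 6.333 in control EVs. LPS EVs held 227.4 ± 118.3 CPM of the same genes, with 14.67 detected. The 7 specific to IL-10 cells summed to 147.4 ± 11.54 there, 44.56 ± 20.49 in IL-10 EVs and 19.34 ± 19.31 in control EVs (exact permutation p = 0.2). Of the 200 genes with the largest rise in LPS cells, 171 were tested in EVs and 93% had the same sign there (59.7% of all genes were positive). Their median EV log2 fold change was 2.47, against -0.61 for the 174 tested of the 200 that fell most, and 50 of the 171 were called higher. After the LPS EV counts were lowered by the median of genes with few cell counts, also chosen afterwards, 149 of the raised genes were tested, 89.3% had the same sign (54.9% of all genes were positive), the median was 1.94 and edgeR called 0. With the larger silent-gene median it was 74.2% of 97 genes (38.5% of all), a median of 1.38 and 0 calls.

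**Figure D4:**
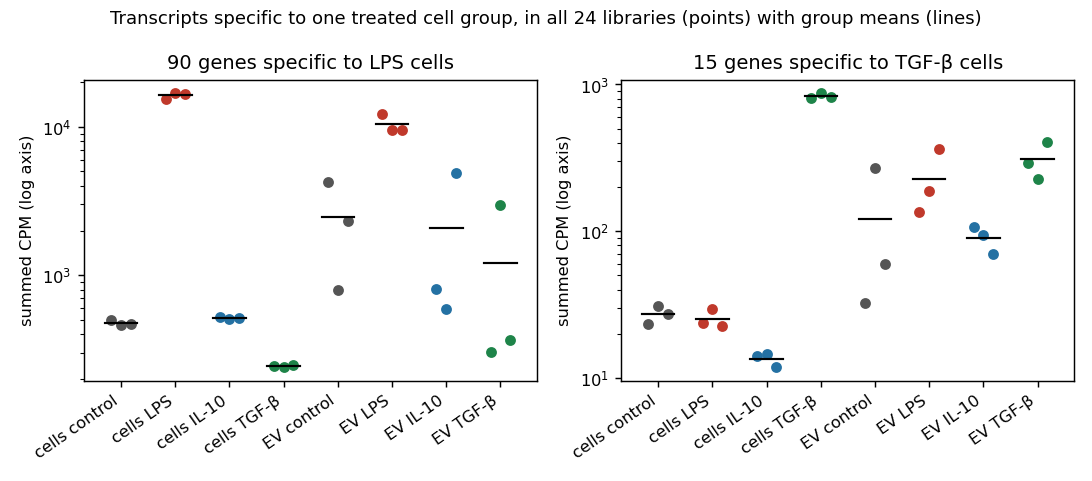
Summed CPM (log axis) of the 90 genes specific to LPS cells (left) and the 15 specific to TGF-β cells (right) in the 8 groups; points are the 24 libraries and lines are group means. LPS EVs (10440 CPM) lie between LPS cells (16240) and control EVs (2461) at the left, and TGF-β EVs (308.1) and LPS EVs (227.4) lie between TGF-β cells (833.4) and control EVs (121.1) at the right.

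Ferritin light chain (Ftl1), an iron storage protein gene singled out after its values were seen, took the largest share of counts in 8 of the 12 EV libraries. It held 0.692% to 1.12% of the counts in cell groups, 5.7% ± 3.83 in control EVs and 3.87% ± 1.32 in LPS EVs (exact permutation p = 0.5). IL-10 EVs had 8.8% ± 2.68 (exact permutation p = 0.4) and TGF-β EVs 15.6% ± 3.64 (p = 0.1, the smallest possible). The heavy chain gene Fth1 took 2.58% of counts in control cells and 3.17%, 3.47% and 1.27% in LPS, IL-10 and TGF-β cells, with 3.76%, 6.13%, 4.06% and 3.18% in EVs in the same order. Both genes have many processed copies in the genome, so their counts are uncertain.

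**Figure D5:**
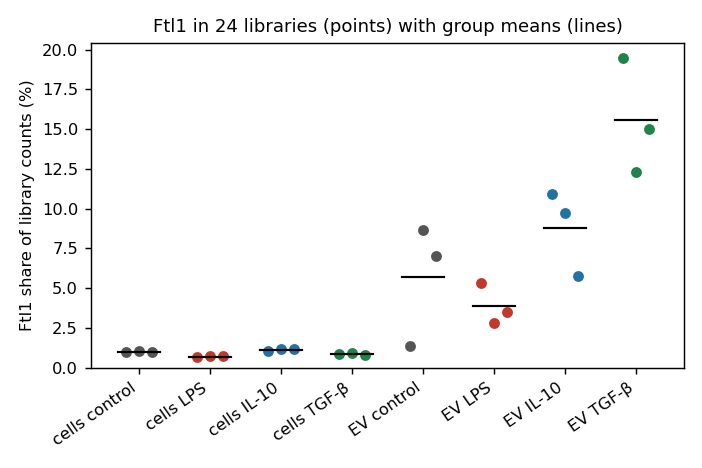
Share of library counts at Ftl1 in percent for the 8 groups; points are the 24 libraries and lines are group means. Cell groups lie at 0.692% to 1.12%, and EV groups at 5.7% (control), 3.87% (LPS), 8.8% (IL-10) and 15.6% (TGF-β).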

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

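Of the tests in this part, the depth test, the exon-length test in genes listed whatever their EV counts and the lowering of LPS EV counts were chosen after the result was seen. Each gene and count below stands out because a treatment's effect differed between cells and EVs in a test of that difference. The log2 differences are fitted values, which depend on the prior count where a group has no count.

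For LPS 2135 genes differed, led in the positive direction by Mcam (18.58), Grin1 (16.94), Slc26a8 (16.71), Sphk1 (16.68) and Tmem117 (16.62) and in the negative direction by Lcn2 (-13.99), Wfdc21 (-10.86), Cfb (-8.03), Fas (-8.01) and Gng7 (-7.72). The size of the Lcn2 value leans on control cell library 2, without which its log2 change in cells was 18.81 in place of 14.35. It also rests on control EVs, which already held Lcn2 at 225 ± 180 CPM against 0.0731 ± 0.127 in control cells. Wfdc21 was likewise higher in control EVs than in control cells. The source of these transcripts in control EVs was not settled. Of 60 splits of the libraries 1, the real one, gave as many genes. The 5 nearest others gave 1738, 1801, 1825, 1852 and, the highest, 1959, and the median of the 59 others was 0. These values argue against chance as the source of the real count, by a narrow lead over 1959. They do not say what set the groups apart. With 1 library left out, 8 of 12 counts (1575 to 1899) lie below 1959. Those counts come from fewer libraries and were not set against splits of the same libraries. They thus cannot show whether the lead hangs on single libraries. With the LPS EV counts lowered by the median of genes with few cell counts 1254 were called, 1002 positive and 252 negative. For IL-10 34 genes differed: Rpap1 (12.97), Cds1 (12.51), R3hcc1 (12.27), Mad1l1 (12.25) and Clmp (11.73) were more positive in EVs, and Itga5 (-14.8), Mctp1 (-14.21), Icam1 (-13.99), Heatr5b (-13.38) and Slc39a13 (-13.04) more negative. As many genes came from 29 of the 60 splits, with 146 as the highest, so chance cannot be excluded. For TGF-β 37 genes differed: Ankrd50 (14.61), Zswim3 (12.91), Ears2 (12.45), Klhl25 (12.44) and Spata6 (11.8) were more positive in EVs, and Ints2 (-12.73), Ms4a6d (-11.85), Ift46 (-11.75), Nt5m (-11.63) and Eefsec (-11.58) more negative. As many came from 21 of the 60 splits, with 182 as the highest, so chance cannot be excluded here either. Splits with several times the real count may point to a structure of the samples, which was not tested.

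LPS EV libraries hold reads at nearly every listed gene, including genes silent in cells such as neuronal markers. Greater depth at the listed genes is argued against. The mean total of the LPS EV libraries was 4.56 M counts, and the lowest control EV total was 5.65 M. LPS EV library 3, at 6.28 M, lay above the latter. Reads outside the listed genes were not at hand, so these totals do not measure all reads sequenced. Passage of transcripts raised in LPS cells is argued against as a general source of the EV calls that could be tested in cells. Of these 840 genes called higher in LPS EVs (863 more were not tested in cells), 29.3% were called higher in LPS cells. The odds ratio was 0.988 (95% interval 0.843 to 1.16). It counts cell rises of any size, so it cannot speak on the largest. Of the 171 tested genes among the 200 that rose most in cells, 50 were called higher in EVs. For all genes tested in both this was 840 of 10974, so passage of the most raised transcripts stays open. A uniform background such as genomic DNA stays open: across 423 genes silent in cells the mean LPS EV count rose with exon length with a Spearman rho of 0.323, but less in single libraries 1 and 3 (0.184, 0.379 and 0.176 in libraries 1 to 3), and control and LPS cells gave 0.145 and 0.154. In 912 genes with few cell counts the rho was 0.4 (0.191, 0.462 and 0.343 per library), against -0.176 in control EVs and 0.049 and 0.026 in control and LPS cells; genes are not independent replicates, and no biological explanation of the pattern beyond the cell response was tested.

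Many genes were at 0 in EV libraries and replicates differed widely. Lower depth is argued against as the whole cause, since control EVs had 3.53 times the share of genes at 0 of control cells thinned to the same totals (31.84% against 9.01%). In all 3 control EV libraries 761 of 10794 genes were at 0, which is 1.86 times the 409.6 expected from independent draws. Few starting RNA molecules and a fixed set of cell transcripts left out of EVs may both contribute and cannot be told apart, because this ratio lies between the bounds set beforehand for each.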

How the results depend on the processing

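In this part the settings with at least 1000 counts and with lowered LPS EV counts were chosen after the data were seen. The counts of called genes in the 6 cell comparisons stayed within 1.5 times under every setting run (DESeq2 and leaving out alone for the last 3), with 1 library left out at 6065 to 6816 (LPS), 1922 to 2834 (IL-10), 2587 to 3857 (TGF-β), 5722 to 6117 (LPS against IL-10), 6195 to 6716 (LPS against TGF-β) and 3853 to 4440 (TGF-β against IL-10). LPS EVs (1732 calls) gave 2685 in DESeq2 (228 lower, against 29), 3038 in limma-voom, 0 with all 12 EV libraries, 0 with at least 50 counts, 7 with at least 1000 counts, 2 with counts lowered by the silent-gene median, 1 with counts lowered per exon base, 0 with counts lowered by the median of genes with few cell counts, and 0 to 2599 with 1 library left out. IL-10 and TGF-β EVs (0 calls) gave 90 and 121 in DESeq2, and 0 to 0 with 1 library left out. Control EVs against cells (1218) gave 3035 in DESeq2 (1185 higher, 1850 lower), 1865 with all 24 libraries, 549 with at least 50 counts and 0 to 4175 with 1 left out. The LPS compartment difference (2135) gave 842 with at least 50 counts, 788 with the silent-gene median removed (186 positive, 602 negative), an amount that overstates a background because EV reads put these genes on the list, 1254 with the median of genes with few cell counts removed (1002 and 252) and 1575 to 3587 with 1 left out. Those for IL-10 (34) and TGF-β (37) gave 703 and 785 in DESeq2 (more positive than negative, unlike edgeR), and 2 to 272 and 3 to 432 with 1 left out. LPS against IL-10 EVs (0) gave 1012 in DESeq2, 2 with the silent-gene median removed and 0 to 0 with 1 left out. LPS against TGF-β EVs (6) gave 1205, 23 (4 with the smaller amount) and 0 to 2, and TGF-β against IL-10 EVs (0) gave 285 in DESeq2 and 0 to 1 with 1 left out.

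Lists passing camera fell with an estimated correlation from 18 to 5 (LPS cells), 15 to 4 (IL-10 cells), 15 to 3 (TGF-β cells), 13 to 0 (LPS EVs), 8 to 0 (IL-10 EVs), 16 to 0 (TGF-β EVs) and 8 to 0 (control EVs against cells), while fry passed 21, 18, 17, 4, 0, 0 and 11. Calls of named genes were lost in 6 (LPS cells), 32 (IL-10 cells), 21 (TGF-β cells), 429 (LPS EVs), 219 (control EVs against cells), 26, 37 and 55 (compartment differences for LPS, IL-10 and TGF-β) and 24 (LPS against TGF-β EVs) gene-by-setting cases, and none reversed. A named gene that a setting did not test was not counted, so these numbers are lower limits on the lost calls. Fewer libraries were tested where 1 was left out, and otherwise the cause of a lost call was not tested. No paired analysis was possible because the columns carry no pairing of replicates. Pseudocount, low-value filter and quantile alternatives for normalized values were not run, since the tables hold counts. With 3.02 to 17.98 M counts a count of 0 in EVs allows up to 0.167 to 0.994 CPM. In LPS EVs, where the spread between libraries beyond counting was 107.5% against 10.3% in LPS cells, 30% of simulated 64-fold changes were recovered, and the part of depth in this was not tested.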

Other observations

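In this part the genes of the first 2 paragraphs and the test on lowered LPS EV counts were chosen after the values were seen. The VEGF receptor Flt1 was at 833 ± 46.3 CPM in TGF-β cells against 166 ± 7.77 in controls, 71.7 after LPS and 124 after IL-10 (n = 3 each), and Cxcr2, which fell after LPS, was at 92 ± 13.1 CPM after TGF-β against 19.5 in controls. Afp, a fetal serum protein gene, was at 166 ± 2.96 CPM in LPS cells against 57.1 ± 2.22 in controls.

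Every EV library lay above every cell library at 329 genes and below at 257, counted across all 24 libraries. Among the former, the lowest EV value was 53.9 CPM for Pdzd2 (highest cell value 5.3), 47.67 for Arl5c (5.13), 34.54 for the Wnt co-receptor Ryk (4.47), 8.4 for Enah (0.57) and 141 for the translation repressor Eif4ebp2 (36.39). Malat1, a nuclear noncoding RNA, was at 300 ± 91 CPM in control EVs against 55.3 ± 9 in control cells.

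Transcripts specific to treated cells appear in control EV libraries, for example Lcn2. Carry-over of reads between finished libraries is argued against in control EV libraries 1 and 3, where 10.44% of 8840 and 9.7% of 5424 genes with at least 100 expected counts were at 0, and stays open in library 2, where 3.33% of 2553 were. RNA of all cell groups mixed in before amplification stays open: the median share of the 3 classes of specific genes differed 10.3-fold, past the 10-fold bound set beforehand, but the IL-10 class has 7 genes of which 3 are at 0 in all control EVs, and the summed shares were 0.538, 0.461 and 0.564. An NF-kB-like state of the cultures that released the control EVs stays open too. LPS-raised cell genes exceeded TGF-β-raised ones by 0.41 in the log2 ratio of control EVs to control cells, short of the bound of 1 set beforehand. Its interval of 0.16 to 0.68 resamples genes, not libraries. Mixing and such a state, these 2, cannot be told apart with these samples.

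A further hypothesis was that EV RNA follows the change of the cells. The intervals in this paragraph resample genes, so they do not measure the spread between libraries. For LPS the 200 most raised and 200 most lowered cell genes differed by 3.08 (95% interval 2.32 to 3.74) in median EV log2 fold change. After the counts were lowered by the median of genes with few cell counts, the difference was 2.83 (2.4 to 3.47). In the counts as deposited the raised list passed camera with an estimated correlation (p = 0.0208) and the lowered list did not (p = 0.0845). These values go with EV RNA following the cells for the raised genes. For IL-10 the difference was 0.04 (-0.38 to 0.35), and for TGF-β 1.9 (1.49 to 2.51), where neither list passed camera with an estimated correlation (p = 0.0535 and 0.219), so both stay open.

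For each comparison of 3 with 3 libraries the 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, so any difference between the groups, whatever its cause, widens its spread and lowers its count. The splits thus cannot tell an effect of treatment from another difference between the groups. Where genes were called, 1 of the 10 splits, the real one, gave as many: 6706 (LPS cells), 2733 (IL-10 cells), 3533 (TGF-β cells), 1732 (LPS EVs), 1218 (control EVs against cells), 6939 (LPS against TGF-β cells) and 6 (LPS against TGF-β EVs) with 0 as the highest other, 6469 with 1 (LPS against IL-10 cells) and 4649 with 2 (TGF-β against IL-10 cells). Where the real count was 0 (IL-10 EVs, TGF-β EVs, LPS against IL-10 EVs and TGF-β against IL-10 EVs), all 10 splits gave 0.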
